A study of Arabidopsis thaliana with 8 samples.

How the data were processed

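Poly(A)-selected RNA was sequenced from dark-grown Arabidopsis thaliana seedlings kept on MS plates for 3 days, in 8 libraries. Per the labels, the seedlings belonged to 2 double-mutant lines of the pyruvate dehydrogenase complex (PDC), e1-2-2 e2-2 (line #17, called e1e2 here) and e2-2 e3-2-2 (line #67, called e2e3 here), and each line was kept in hydrocarbon-free air or in 10 ppm ethylene. The 4 groups held 2 libraries each, as separately numbered replicates. The labels name neither the loci behind e1, e2 and e3 nor the hours of ethylene, and no sequencing batch is given. RNA was extracted with an RNeasy kit and the libraries were made with an NEBNext poly(A) module and Ultra II RNA kit, per the labels' protocols. No wild-type libraries were analysed here.

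The authors deposited gene counts, which are whole numbers of read pairs per gene with no normalization. Per the file headers these counts came from featureCounts 2.0.1 on the Araport11 genes and transposons, with paired-end counting and no strand setting, and with neither the option for multi-mapping reads nor that for reads over several genes. By the program's defaults, reads that map to several places and reads over more than 1 gene were left out. The submitters' processing notes also name TAIR10, FastQC, Trim Galore, STAR, Subread 2.0.1 and DESeq2, without their roles or order. The STAR and Trim Galore settings are not given in the sources used here. This counting affects genes with near-identical copies, such as the LHCB1 and RBCS families, the GSTF6 and GSTF7 pair and the HSP17.6II and HSP17.6A pair, whose values are uncertain. It also removes reads over overlapping or antisense genes: 1466 of the 36799 genes in the tables had at least 90% of their exonic bases under another gene, and 4 of these were tested.

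The authors' deposited DESeq2 tables, 1 per line, give a mean signal per gene (counts divided by size factors and averaged over the 4 libraries of the line), a log2 fold change between air and ethylene with its standard error, and a p-value with its adjusted value. Their design formula and DESeq2 version are not given in the sources used here. Another deposited table lists genes that the authors called in wild type, with log2 fold changes in wild type and in both mutants. From its values, no wild-type change in it is under 2-fold, and its mutant columns equal those of the DESeq2 tables. All tests below were run on the counts, and values from these tables are named as the authors'.

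Symbols came from the TAIR10.1 RefSeq gene table, which held 36632 of the 36799 loci and gave a symbol to 10505. Coordinates are those of the count tables on TAIR10. Where the table gives no symbol, the locus is printed. Several symbols are shared by unrelated genes, and the locus is then given beside the name.

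Differences were tested with edgeR 4.0.16 in R 4.3.3, using robust quasi-likelihood fits and F-tests after TMM scaling and the default expression filter by group, which left 20193 genes. All 8 libraries entered 1 fit of 4 groups, so that they share an estimate of the spread (4 residual degrees of freedom). The fit also borrows spread across genes, with a median prior of 218 degrees of freedom. The p-values therefore rest mostly on spread shared by genes rather than on each gene's own. The common biological coefficient of variation, the spread beyond counting noise, was 2.75%. The contrasts were ethylene against air in e1e2, ethylene against air in e2e3, the difference of these responses (e2e3 minus e1e2), and e2e3 against e1e2 in air and in ethylene. The difference of responses uses the same air libraries as the lines in air, with opposite sign, so these results are not independent of each other. P-values were adjusted by Benjamini-Hochberg over the genes tested, and a gene was called at an adjusted p under 0.05. A standard error is the log2 fold change divided by the square root of its F. Levels are CPM over TMM-scaled library sizes, given as mean ± SD.

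Before the data were examined, 20 gene lists with 286 entries were fixed, together with the groups, contrasts, tests, named-gene rule and alternatives. The lists cover mitochondrial and plastid PDC subunits, ethylene perception and signalling, ethylene response, ethylene biosynthesis, auxin, expansins and xyloglucan endotransglucosylases, root hairs, root tissue, photosynthesis and chlorophyll synthesis, light response, mitochondrial stress, acetyl-CoA and the TCA cycle, hypoxia and fermentation, histone acetyltransferases and deacetylases, jasmonate, salicylate and defence, heat shock, touch and handling, and seed storage and late embryo. Lists with at least 3 tested members were compared with all other genes by camera (limma 3.58.1) with a preset inter-gene correlation of 0.01, in every contrast except the genotypes in ethylene, and adjusted over the lists. Camera with an estimated correlation and fry, which tests only whether a list's own genes move one way on balance, were alternatives. The correlation was estimated with the 4 residual degrees of freedom of the fit. Lists with a negative estimate lost calls too. A call lost under this alternative therefore does not by itself show that the list's genes are correlated. Member counts refer to the test over all genes, and the count adjusted over the list alone is given where it differs.

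The rule for named genes took, per ethylene contrast, the mitochondrial PDC subunits, the 6 largest rises and the 6 largest falls among called genes with a symbol, a mean of at least 5 CPM and groups that did not overlap, up to 3 called members per list with the smallest adjusted p, and EBF2, ERF1, HLS1, ETR2 and EIN2. The other contrasts took the 5 largest each way and the list members. Any other gene named in the text was chosen after its values were seen. The results of some genes under this rule are not reported here. Another 4 lists (storage-oil breakdown, camalexin and indole-derived defence, microbe-pattern response, iron deficiency) and groups of genes sharing a symbol stem were made after the genotype contrast had been looked at. The ferritin genes FER1 (log2 difference in air 0.145 ± 0.035) and FER4 (0.065 ± 0.06), which iron raises, were taken out of the iron-deficiency list before it was tested.

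The edgeR steps were tested on simulated data with 20193 genes, drawn from each gene's mean over all 8 libraries and from the libraries' sizes. Of these genes, 50 were changed by each known fold for ethylene in each line (100 for the difference of responses). The changed genes were not taken from those of very low expression. For ethylene in e1e2, 52% of genes changed 1.25-fold, 80% of those changed 1.5-fold and 94% of those changed 2-fold were recovered, with 8 false calls. For ethylene in e2e3 these shares were 42%, 86% and 90%, with 15 false calls. For the difference of responses they were 28%, 62% and 83%, with 14 false calls. Far fewer genes were changed in the simulation than were called for ethylene in the real data, so these rates may not carry over. Simulated spread followed the fitted trend, with no scatter of single genes around it, so the rates may be too favourable. A simulated raised list gave a camera p of 3.04e-18 and an unchanged list 0.774. Genes were simulated independently, so this does not check the preset correlation.

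Alternatives were DESeq2 1.42.0, RLE factors, library size with no composition factor, other low-count filters, fits of the compared libraries alone, a replicate block, organellar genes left out, and each library left out in turn. Total counts per library ran from 11522823 to 18601837, which sets the counting error of low genes. Exact binomial intervals at 95% and the floor of 3 counts over a group cover counting error only. The authors' text description of their files holds no measurement and was not used. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.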

Results

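Gene expression was measured in 8 libraries of 3-day-old dark-grown Arabidopsis seedlings. They came from 2 double mutants of the pyruvate dehydrogenase complex (PDC), the enzyme that makes acetyl-CoA from pyruvate. Each line, e1e2 (e1-2-2 e2-2) and e2e3 (e2-2 e3-2-2), was grown in air and in 10 ppm ethylene, with 2 libraries per group. By its title, the series concerns PDC in the nucleus, acetylation of histones directed by EIN2, and the transcription that ethylene sets off. Total counts were 11522823 and 12728015 for e1e2 in air, 14325334 and 14033113 for e1e2 in ethylene, 14480759 and 18601837 for e2e3 in air, and 14075249 and 14206221 for e2e3 in ethylene. The 10 most abundant genes held 4.67% to 5.34% of the counts. Replicates differed by more than counting noise in each group (mean chi-square per gene from 1.42 to 1.99), and their log CPM correlated at 0.991 to 0.9933 across genes. The labels do not say whether replicates were separate plantings. The p-values thus measure only the spread between these samples, estimated mostly across genes, and this spread may be technical. The first principal component (64.7% of the variance) separated ethylene from air and the second (11.4%) separated the lines.

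The targeted complex was examined first. Among its subunit genes, E1 ALPHA (AT1G59900, chromosome 1, 22051133 to 22053885, a gene for an E1 alpha subunit of mitochondrial PDC) differed most between the lines. Its values were 23.1 and 22.1 CPM in the e1e2 air libraries and 20.2 and 19.2 CPM in the e1e2 ethylene libraries, against 229.9, 230.6, 216 and 214 CPM in e2e3. The opposite held for mtLPD2 (AT3G17240, chromosome 3, 5889663 to 5892332, a gene for the E3 dihydrolipoyl dehydrogenase subunit), which read 138, 131, 149 and 150.3 CPM in e1e2 against 27.4, 27.9, 36.4 and 40.4 CPM in e2e3. In air the difference was 10.2-fold for E1 ALPHA and 4.85-fold for mtLPD2. The E2 genes showed no such gap: LTA3 lay between 83.4 and 94.9 CPM, AT3G13930 between 167 and 198 CPM and AT1G54220 between 17.05 and 20.5 CPM over the 8 libraries. Both lines carry e2-2, so comparing them does not check that label, and the labels do not tie allele names to loci.

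**Figure D1:**
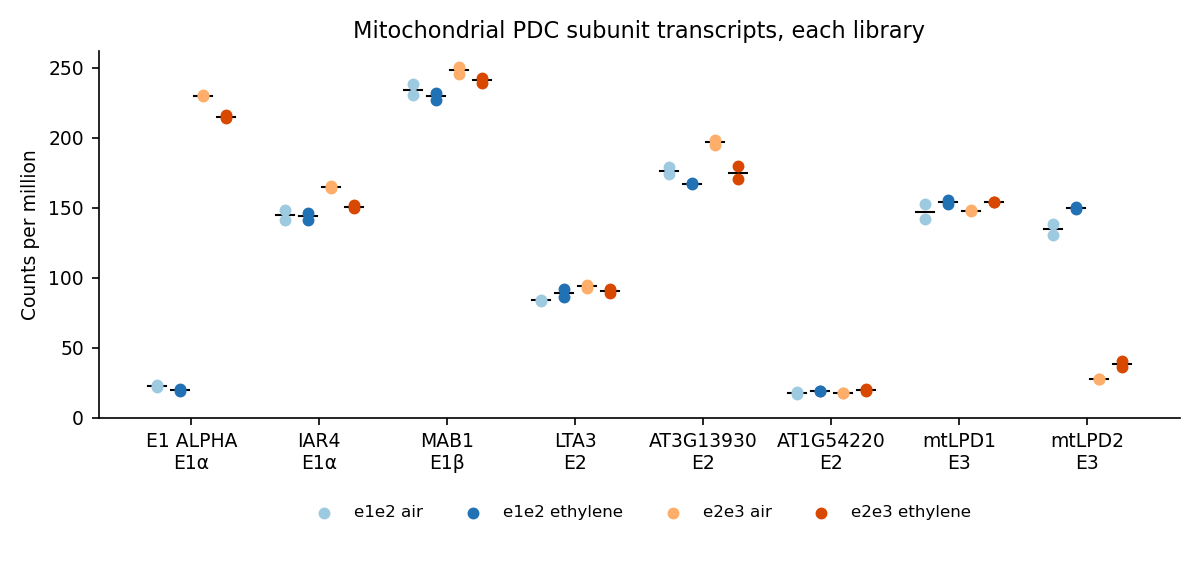
Expression of the 8 mitochondrial PDC subunit genes in CPM, with each library as a point and each group mean (n = 2) as a bar. E1 ALPHA lies at 19.2 to 23.1 CPM in e1e2 and 214 to 230.6 CPM in e2e3, and mtLPD2 at 131 to 150.3 CPM in e1e2 and 27.4 to 40.4 CPM in e2e3.

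Ethylene moved the other PDC genes little. In e1e2, 1 of the 8 mitochondrial subunits rose (mtLPD2, log2 change 0.16 ± 0.05, SE), and 7 did not pass the test. This rise did not pass DESeq2. In e2e3, mtLPD2 rose by 0.47 ± 0.07, AT3G13930 (−0.17 ± 0.04), IAR4 (−0.13 ± 0.04) and E1 ALPHA (−0.10 ± 0.04) fell, and 4 did not pass. None of the 3 falls passed with library size alone, and IAR4 and E1 ALPHA did not pass DESeq2 and kept their call in 5 and 1 of the 8 fits that left out a library. Among 7 plastid subunits, PDH-E1 BETA fell in e1e2 (−0.38 ± 0.05) and e2e3 (−0.48 ± 0.05), while LPD1 (0.26 and 0.16) and AT4G16155 (0.25 and 0.31) rose in both. The rise of LPD1 in e2e3 did not pass DESeq2 and was kept in 5 of the 8 fits that left out a library, and that of AT4G16155 in e1e2 in 6. In total 3 plastid subunits rose and 2 fell in e1e2, and 2 rose and 1 fell in e2e3. Neither list passed camera in either line (adjusted p from 0.853 to 1).

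In e1e2 seedlings, ethylene raised 15 and lowered 2 of 17 ethylene response genes, raised 5 and lowered 12 of 24 auxin genes, and raised 2 and lowered 18 of 22 listed expansin and xyloglucan endotransglucosylase genes. EFE (AT1G05010, the ACC oxidase ACO4, which makes ethylene from ACC, on chromosome 1 from 1431177 to 1433010) rose 6.88-fold, from 115.6 ± 2.93 to 794.5 ± 13.3 CPM (SD, n = 2 per group). The carbonic anhydrase gene BCA3 rose 16.3-fold, the expansin gene EXPA12 13.1-fold, EARLI1 10.8-fold and the glycosyl hydrolase gene GH9B12 7.77-fold. DXPS1 had 3 counts in air and 350 in ethylene, a ratio of 95.3 (exact 95% interval 32.3 to 464). IAA6, an auxin-induced repressor gene, fell 14.3-fold, from 27.8 ± 3.46 to 1.94 ± 0.117 CPM. The expansin genes EXPA5 (10.7-fold) and EXPB1 (7.55-fold), the cytochrome P450 gene CYP71A16 (7.96-fold), the arabinogalactan gene AGP22 (7.81-fold) and the pectin methylesterase gene PME61 (7.59-fold) fell as well.

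Of 17 tested ethylene response genes in e1e2, 15 rose and 2 fell, with a median log2 change of 1.69. The growth regulator ARL rose by 2.08 ± 0.05, the transcription factor genes TEM1 by 1.61 ± 0.04 and EBP (RAP2.3) by 1.70 ± 0.05, and the hook gene HLS1 by 1.08 ± 0.07. ERF1, a factor downstream of EIN3, went from 7 to 156 counts (log2 ratio 4.19, exact 95% interval of the ratio 8.63 to 46), and HCHIB (PR3) fell by 0.35. This list passed camera (Benjamini-Hochberg adjusted p = 6.63e-10, and adjusted p = 0.043 with an estimated correlation). Of 17 perception and signalling genes, 11 rose and 3 fell (camera adjusted p = 0.000777, and adjusted p = 0.106 with an estimated correlation). The rises included the receptors ETR2 (1.78 ± 0.07), ERS1 (1.14 ± 0.04) and ERS2 and the negative regulators CTR1 (1.37 ± 0.04), RTE1 and EBF2 (0.85 ± 0.04), along with the central activator EIN2, which rose 1.54-fold from 360.8 ± 4.97 to 556.4 ± 2.87 CPM. EIL1, RAN1 and AT3G11100 (ENAP1) fell. Of 13 biosynthesis genes, 4 rose and 7 fell (camera adjusted p = 0.953). The 4 rises were ACC oxidases, including EFE and AT1G77330 (0.65 ± 0.04). Of the 7 falls, 5 were ACC synthases, with ACS8 at −2.69. The others were the ACC oxidase AT1G12010 (−0.43) and ETO1 (−0.19).

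Genes of hormone and growth programmes moved with them in e1e2. Of 22 expansin and xyloglucan endotransglucosylase genes, 18 fell and 2 rose, among them EXPB1 (−2.92 ± 0.11) and XTH4 (−1.37 ± 0.04), with a camera adjusted p of 9.38e-08, and adjusted p = 0.183 with an estimated correlation. The fixed list holds part of the family: of all 25 genes with an XTH symbol, a group formed after the data were seen, 11 rose and 10 fell. Of 24 auxin genes, 12 fell (13 adjusted over the list alone) and 5 rose, with IAA19 at −2.03 ± 0.06 and the auxin carrier PIN3 at −0.52 ± 0.04 (camera adjusted p = 0.0177, and adjusted p = 0.183 with an estimated correlation). Seed storage and late embryo genes fell in 13 of 16 cases, such as EM1 (−1.34 ± 0.06), RAB18 (−0.50 ± 0.04) and OLEO2 (−0.75 ± 0.07), with a camera adjusted p of 8.33e-07, and adjusted p = 0.196 with an estimated correlation. Hypoxia and fermentation genes rose in 11 of 13 cases, with the haemoglobin gene HB1 at 2.15 ± 0.15, the oxidase gene AT5G15120 (PCO1) at 1.53 ± 0.14 and ADH1 at 1.03 ± 0.11 (camera adjusted p = 0.000201, and adjusted p = 0.106 with an estimated correlation). Of 13 root hair genes, 8 rose (9 adjusted over the list alone) and 2 fell, led by PRP1 (1.26 ± 0.08) and RHS18 (1.08 ± 0.12), with a camera adjusted p of 0.0177, and adjusted p = 0.196 with an estimated correlation. Beside them, 6 of 11 root tissue markers fell, including CASP5 (−1.04 ± 0.05) and PYK10 (−0.65 ± 0.03), and this list did not pass camera (adjusted p = 0.0555). Jasmonate response genes fell in 4 of 7 tested cases, with the storage protein genes VSP2 at −1.78 ± 0.16 and VSP1 at −0.70 ± 0.12 (camera adjusted p = 0.0465, and adjusted p = 0.471 with an estimated correlation).

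The remaining lists went both ways or stayed short of the camera threshold in e1e2. Photosynthesis and chlorophyll genes rose in 9 and fell in 12 of 30 cases (10 and 13 adjusted over the list alone), with the antenna genes LHCB2.1 at −0.90 ± 0.05 and LHCA4 at −0.47 ± 0.03, and the Rubisco small-subunit gene RBCS1B, which has near-identical copies, at 0.86 ± 0.07 (camera adjusted p = 0.912). TCA and acetyl-CoA genes rose in 6 and fell in 2 of 15 cases, with FUM1 at 0.61 ± 0.04 and the ATP-citrate lyase gene ACLB-2 at −0.38 ± 0.04 (0.85). Mitochondrial stress markers rose in 3 and fell in 1 of 10 cases, with the small heat-shock gene AT5G51440 at 0.75 ± 0.13 and BCS1, which did not pass DESeq2, at −0.44 ± 0.14 (0.64). Histone acetyltransferase and deacetylase genes rose in 3 of 15 cases (2 adjusted over the list alone), namely HAC1 (0.23 ± 0.05), HDA9 (0.39 ± 0.12) and HAM1 (0.21 ± 0.09), with a camera adjusted p of 0.112. DESeq2 called 1 of them, HAC1. Light markers rose in 2 and fell in 1 of 7 cases (ELIP1, 1.29 ± 0.15), touch genes rose in 2 and fell in 3 of 8 (TCH2, −0.67 ± 0.08), heat-shock genes rose in 2 and fell in 1 of 8 (HSP70, 0.22 ± 0.05), and salicylate genes rose in 2 of 5 (WRKY70, 0.87 ± 0.18). None of these passed camera (adjusted p from 0.117 to 0.912). The camera direction differed from the sign of the median or mean for the plastid PDC, biosynthesis, light, TCA and heat-shock lists, none of them past the test.

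By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 3694 genes rose and 4217 fell in e1e2 out of 20193 tested, of which 423 and 898 changed at least 2-fold. EFE had the smallest adjusted p of these named genes (edgeR quasi-likelihood, Benjamini-Hochberg, 3.69e-147). DESeq2 on the same counts called 5137 genes, and with library size alone 5220 were higher and 3492 lower, a shift of 0.067 in the median log2 change. In the list tests, the ethylene response list held its call with an estimated correlation in both lines, and no other fixed list did in any comparison.

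In e2e3, ethylene raised EFE 6.23-fold, from 131.7 ± 4.54 to 822.5 ± 18.8 CPM (SD, n = 2 per group), EXPA12 30.5-fold, EARLI1 19.6-fold, BCA3 15.6-fold and the defence-priming gene AZI1 6.25-fold. GSTU3, a glutathione transferase gene, went from 12 to 279 counts, a ratio of 25.7 (exact 95% interval 14.5 to 50.3). IAA6 fell 10.2-fold, EXPA17 9.86-fold, CYP71A16 9.0-fold, ICS2, which encodes an isochorismate synthase, 8.78-fold, EXPB1 8.16-fold and AGP22 8.08-fold. The fixed response genes ETR2 (1.63 ± 0.06), EBF2 (0.73 ± 0.04), HLS1 (1.08 ± 0.06) and EIN2 (0.46 ± 0.04) rose, and ERF1 went from 13 to 109 counts, a ratio of 9.26 (5.2 to 18).

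Of the 17 ethylene response genes, 15 rose and 1 fell in e2e3, with ARL at 1.88 ± 0.05, TEM1 at 1.61 ± 0.04 and EBP at 1.61 ± 0.05 (camera adjusted p = 2.4e-09, and adjusted p = 0.048 with an estimated correlation). Perception and signalling genes rose in 10 cases (11 adjusted over the list alone) and fell in 4 of 17, with CTR1 at 1.24 ± 0.04 and ERS1 at 1.04 ± 0.04 (camera adjusted p = 0.00184, and adjusted p = 0.164 with an estimated correlation). Biosynthesis genes rose in 4 and fell in 7 of 13 cases, again ACC oxidases such as ACO1 (AT2G19590, 1.59 ± 0.10) against ACC synthases such as ACS8 (−2.11), with a camera adjusted p of 0.515. Expansin and xyloglucan genes fell in 17 and rose in 2 of 22 cases, with EXPA8 at −1.84 ± 0.04 and XTH4 at −1.38 ± 0.03 (camera adjusted p = 4.94e-06, and adjusted p = 0.236 with an estimated correlation). Auxin genes fell in 15 cases (16 adjusted over the list alone) and rose in 4 of 24, with IAA19 at −1.84 ± 0.05 and PIN3 at −0.64 ± 0.04 (camera adjusted p = 0.00717, and adjusted p = 0.171 with an estimated correlation). Hypoxia genes rose in 8 of 13 cases (9 adjusted over the list alone), with HB1 at 1.88 ± 0.14 and AT5G15120 at 1.76 ± 0.15 (camera adjusted p = 0.00303, and adjusted p = 0.164 with an estimated correlation).

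Photosynthesis and chlorophyll genes rose in 20 of 30 cases and fell in 5 (6 adjusted over the list alone) in e2e3. RBCS3B rose by 0.60 ± 0.03, RBCS1B by 1.17 ± 0.07 and PORA, a protochlorophyllide reductase gene, by 0.43 ± 0.03 (camera adjusted p = 0.00147, and adjusted p = 0.619 with an estimated correlation). Heat-shock genes rose in 5 of 8 cases, with HSP70 at 0.63 ± 0.05 and HSP90.1 at 0.60 ± 0.08 (camera adjusted p = 0.039, and adjusted p = 0.29 with an estimated correlation). Seed storage and late embryo genes fell in 9 of 16 cases, with OLEO2 at −1.20 ± 0.06 and EM1 at −1.03 ± 0.06 (camera adjusted p = 0.00147, and adjusted p = 0.425 with an estimated correlation). Root hair genes rose in 7 and fell in 2 of 13 cases (camera adjusted p = 0.27), with PRP1 at 1.26 ± 0.07 and the oxidase gene RHD2 at −0.65 ± 0.08. Beside them, root tissue markers fell in 6 of 11 cases (0.111), with CASP5 at −1.06 ± 0.04 and PYK10 at −0.70 ± 0.03. Jasmonate genes rose in 1 and fell in 3 of 7 cases (VSP2, −1.85 ± 0.15), touch genes rose in 2 and fell in 4 of 8 (WRKY40, 1.04 ± 0.20), TCA genes rose in 3 and fell in 5 of 15, or 6 adjusted over the list alone (FUM1, 0.57 ± 0.04), and mitochondrial stress markers rose in 3 and fell in 2 of 10 (BCS1, −0.85 ± 0.12). Light markers rose in 2 of 7 cases (ELIP1, 1.61 ± 0.14) and salicylate genes in 1 of 5 (PAD4, 0.62 ± 0.18, which did not pass DESeq2). Histone acetyltransferase and deacetylase genes rose in 2 of 15 cases, HD1 (HDA19, 0.13 ± 0.04) and HAC1 (0.12 ± 0.05). Adjusted over the list alone none of these 15 passed, while 3 did by edgeR at an unadjusted p under 0.05 and 0 by DESeq2. None of the 7 lists from jasmonate on passed camera (adjusted p from 0.27 to 0.951), and the median of the mitochondrial PDC and light lists differed in sign from their mean or test.

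edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 4109 genes higher and 4767 lower in ethylene in e2e3, of which 402 and 965 changed at least 2-fold. With library size alone these were 5874 and 3773, with the median shifted by 0.082.

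**Figure D2:**
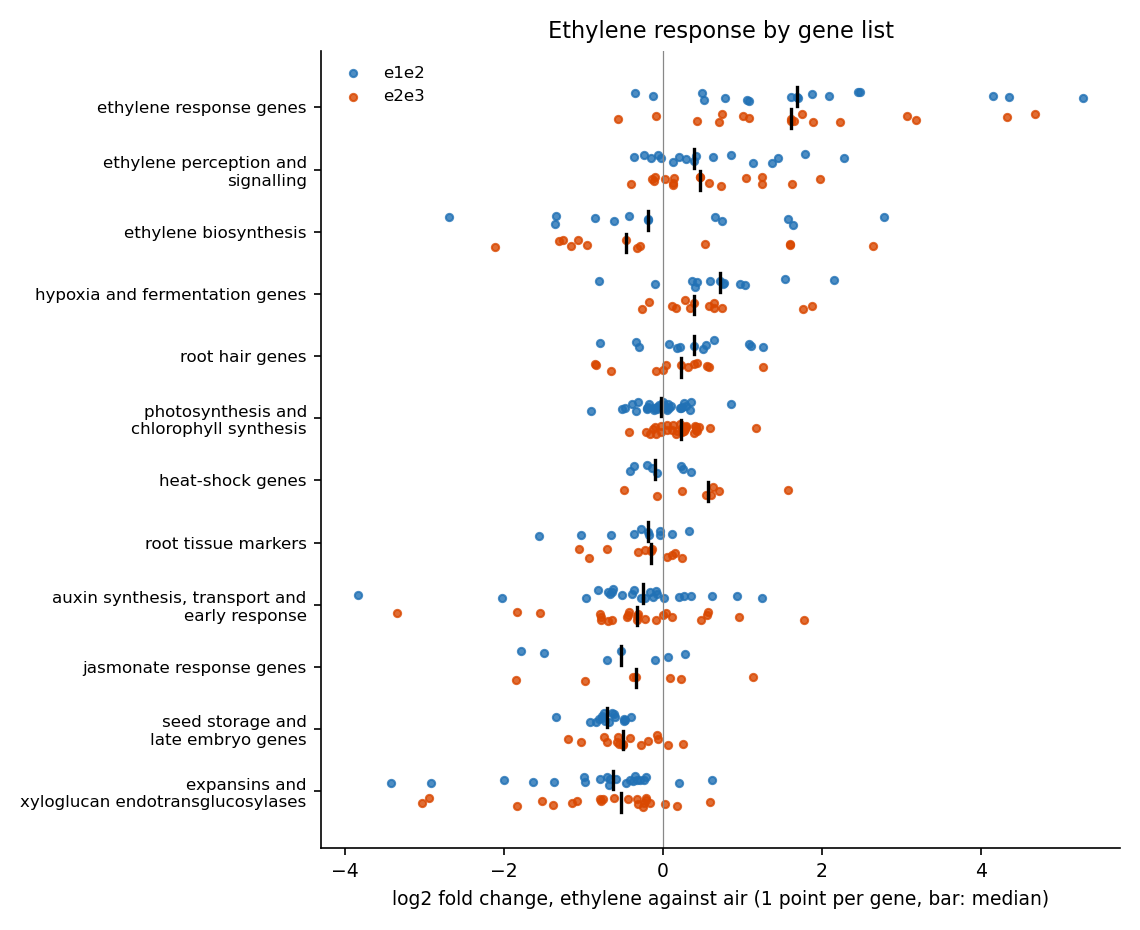
Log2 fold change in ethylene against air for each tested gene of 12 fixed lists, with e1e2 in blue, e2e3 in orange and a bar at each list's median. The ethylene response list has medians of 1.69 and 1.61, and the expansin and xyloglucan list −0.63 and −0.53.

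The calls of the lines overlapped widely. Of the genes called in both lines, 2584 rose in both and 3503 fell in both, where independent lists of these lengths would share 752 and 996. Another 30 were called in opposite directions, among them the cold- and abscisic-acid-induced gene KIN2. A further 1794 genes passed in e1e2 alone and 2759 in e2e3 alone, which does not show that their responses differed. Across all tested genes, which are not independent replicates, the log2 changes correlated at 0.814 (Pearson) and 0.736 (Spearman), and the lines' contrasts used different libraries.

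**Figure D3:**
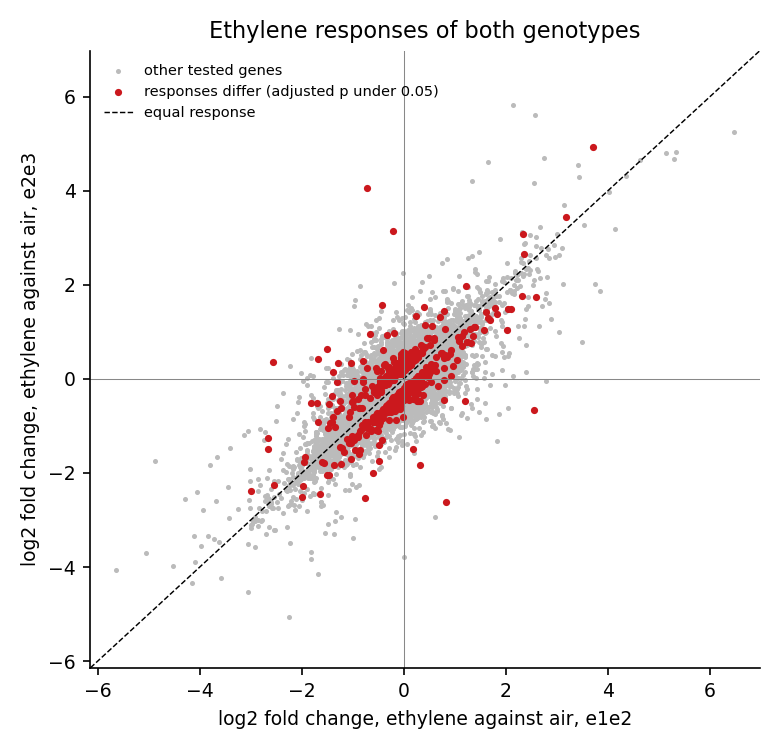
Log2 fold change in ethylene for each tested gene in e1e2 (x axis) and e2e3 (y axis), with the dashed line at equal responses and red points for the 566 genes whose responses differ by edgeR's quasi-likelihood test. Most genes lie along the dashed line, with a Pearson correlation of 0.814.

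Whether ethylene acted differently in the lines was tested directly as e2e3 response minus e1e2 response. Photosynthesis genes stood out: 21 of 30 (27 adjusted over the list alone) had a higher response in e2e3, and none a lower one. LHCB2.1 fell by 0.90 in e1e2 and by 0.43 in e2e3, a difference of 0.47 ± 0.07. LHCA3 fell by 0.12 in e1e2 and rose by 0.21 in e2e3, a difference of 0.33 ± 0.05, and CAB1 (LHCB1.3), which has near-identical copies, changed by −0.18 and 0.12. AT4G33070 (PDC1), a pyruvate decarboxylase gene of fermentation, rose from 12.4 ± 0.766 to 24.3 ± 0.283 CPM in e1e2 and from 48.3 ± 1.53 to 58.9 ± 1.72 CPM in e2e3, a difference of −0.69 ± 0.13 on the log2 scale. KIN2 fell from 218.5 ± 5.3 to 148.8 ± 2.2 CPM in e1e2 and rose from 165.3 ± 1.53 to 192.6 ± 13.5 CPM in e2e3.

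The photosynthesis list passed camera for this difference (adjusted p = 5.97e-15, and adjusted p = 0.335 with an estimated correlation). No member had a lower response in e2e3 at an unadjusted p under 0.05 by edgeR or at an adjusted p under 0.05 by DESeq2. Heat-shock genes had a higher response in e2e3 in 2 of 8 cases (5 adjusted over the list alone), HSP70 (0.41 ± 0.07) and HSP17.6II (1.99 ± 0.55, at 0.602 to 1.98 CPM and with a near-identical neighbour), with a camera adjusted p of 0.000785, and adjusted p = 0.335 with an estimated correlation. Seed storage and late embryo genes had a higher response in 2 cases (4 adjusted over the list alone), SESA2 (0.74 ± 0.14) and EM1 (0.31 ± 0.08), and a lower one in OLEO2 (−0.45 ± 0.09), with a camera adjusted p of 0.0123, and adjusted p = 0.527 with an estimated correlation. Root hair genes passed camera downward with a median of −0.21 (adjusted p = 0.00417, and adjusted p = 0.335 with an estimated correlation), although no single member passed edgeR over all genes. Of these 13, 5 were lower adjusted over the list alone, 6 at an unadjusted p under 0.05 and 0 by DESeq2. DESeq2's own filter leaves genes without an adjusted p, and only 2 of these 13 had one.

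Among perception and signalling genes, AT3G11100 (ENAP1, 0.39 ± 0.11) had a higher response in e2e3, and EBF1 (−0.25 ± 0.08) and EIN2 (−0.17 ± 0.05) a lower one (3 lower adjusted over the list alone and 0 by DESeq2). EBF1 and EIN2 passed neither DESeq2 nor the fit with RLE factors, and EBF1 did not pass with library size alone. The ACC oxidase gene AT1G12010 had a lower response (−0.88 ± 0.25) and mtLPD2 a higher one (0.32 ± 0.09). With AT4G33070 these were the only other list members past the test. Their lists, perception, biosynthesis, mitochondrial PDC and hypoxia, did not pass camera (adjusted p from 0.0603 to 0.914). In 13 lists (plastid PDC, ethylene response, auxin, expansin, root hair, root tissue, light, mitochondrial stress, TCA, histone acetylation, jasmonate, salicylate and touch) edgeR called 0 of 161 members, against 32 at an unadjusted p under 0.05, 10 adjusted over the list alone and 0 by DESeq2. DESeq2's filter left many of these members without an adjusted p, so its 0 says little about them. It gave one to 2 of 13 root hair, 8 of 24 auxin and 0 of 7 light genes, but to 15 of 15 TCA genes. Apart from root hair genes, none of these lists passed camera (adjusted p from 0.264 to 0.923). Medians of the mitochondrial PDC, plastid PDC, auxin, root tissue, mitochondrial stress and touch lists differed in sign from their mean or test. Among called genes with a symbol, a mean of at least 5 CPM and groups that did not overlap, the 5 largest differences each way were EXPA12 (1.22 ± 0.35), MLP31 (0.79 ± 0.23), KIN2 (0.78 ± 0.06), EPR1 (AT1G18330, a clock-related factor, 0.77 ± 0.14) and SESA2 upward and, downward, the repair gene SNM1 (−0.82 ± 0.21), the wax gene CER4 (−0.81 ± 0.21), the methyltransferase gene PXMT1 (−0.79 ± 0.11), the glutathione transferase gene GSTF6 (−0.79 ± 0.19) and ATCSLB05 (−0.71 ± 0.20).

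edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 566 genes, 310 higher and 256 lower in response (397 and 196 with organellar genes left out), with 23 and 9 of at least 2-fold. The larger response was in e2e3 for 373 genes and in e1e2 for 193. The count was 220 with DESeq2, whose own filter left 186 of the 566 without an adjusted p, and it fell to 263 without e1e2 ethylene replicate 1, 240 without e1e2 ethylene replicate 2, 367 without e2e3 air replicate 1 and 242 without e2e3 ethylene replicate 2. Of the named genes, KIN2, EPR1, SESA2, PXMT1, LHCB2.1, LHCA3, CAB1, AT4G33070, HSP70 and OLEO2 kept their call whichever library was left out, while of these 8 fits EIN2 kept it in 1, EBF1, MLP31 and ATCSLB05 in 2, EXPA12, AT1G12010 and HSP17.6II in 3, and the other 6 in 4 to 6.

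The lines also differed in air, without added ethylene. Beyond E1 ALPHA (log2 difference, e2e3 minus e1e2, 3.35 ± 0.06), AT4G33070 was 3.9-fold higher in e2e3, PXMT1 3.69-fold, the cytochrome P450 gene CYP716A2 3.39-fold, GSTF6 3.24-fold and GSTU25 2.44-fold (n = 2 per group). Beyond mtLPD2 (−2.28 ± 0.06), the iron-uptake genes FRO2, a ferric reductase, and IRT1, an iron transporter, were 4.38-fold and 3.54-fold lower, the glycine-rich protein gene GRP9 3.89-fold and the glyoxalase gene GLYI4 2.64-fold. IRT1 went from 40.4 ± 1.68 CPM in e1e2 to 11.4 ± 0.398 CPM in e2e3.

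Photosynthesis and chlorophyll genes were lower in e2e3 in 29 of 30 cases (all 30 adjusted over the list alone), with a median of −0.33. CAB1 differed by −0.48 ± 0.03, CAB2 (LHCB1.1), which has near-identical copies, by −0.69 ± 0.05, and LHCA1 by −0.48 ± 0.04 (camera adjusted p = 7.72e-21, and adjusted p = 0.299 with an estimated correlation). Root hair genes were higher in 11 of 13 cases, with PRP3 at 0.67 ± 0.05 and LRX1 at 0.66 ± 0.07 (camera adjusted p = 1.37e-06, and adjusted p = 0.215 with an estimated correlation). Beside them, 6 of 11 root tissue markers were higher, with CASP1 at 0.36 ± 0.04 and PYK10 at 0.23 ± 0.03 (camera adjusted p = 0.0548). Expansin and xyloglucan genes were higher in 11 (12 adjusted over the list alone) and lower in 1 of 22 cases, with EXPA8 at 0.54 ± 0.04 and XTH4 at 0.45 ± 0.03 (camera adjusted p = 0.00127, and adjusted p = 0.311 with an estimated correlation). TCA and acetyl-CoA genes were higher in 5 of 15 cases, including the aconitase gene ACO3 (AT2G05710, 0.26 ± 0.03), with a camera adjusted p of 0.0333, and adjusted p = 0.42 with an estimated correlation. Mitochondrial PDC genes were higher in 4 and lower in 1 of 8 cases, with IAR4 (0.18 ± 0.04), LTA3 and AT3G13930 beside E1 ALPHA and mtLPD2 (0.139).

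Other lists did not pass camera in air (adjusted p from 0.0548 to 0.94). Higher in e2e3 were 4 of 24 auxin genes (5 adjusted over the list alone), among them the auxin-conjugating genes GH3.3 (0.86 ± 0.10) and DFL1 (0.43 ± 0.06), 3 of 13 biosynthesis genes (EFE, 0.19 ± 0.05), 2 of 10 mitochondrial stress markers (BCS1, 0.76 ± 0.12), 2 of 13 hypoxia genes (the lactate dehydrogenase gene AT4G17260, 0.32 ± 0.10), or 1 by DESeq2, and 1 of 15 histone acetylation genes (HDA6, 0.24 ± 0.08). AT4G17260 and HDA6 passed neither DESeq2 nor the fit with library size alone, and HDA6 did not pass adjusted over the list alone. Lower was 1 of 7 light markers, ELIP2 (−0.71 ± 0.19), or 2 adjusted over the list alone. Lists that went both ways were perception (1 higher, 2 lower, with AT3G11100, which did not pass DESeq2, at −0.27 ± 0.07), ethylene response (2 higher, or 4 adjusted over the list alone, and 1 lower, with HCHIB at 0.26 ± 0.06), heat shock (1 higher and 3 lower, or 2 and 5 adjusted over the list alone, with HSP70 at −0.29 ± 0.05), touch (1 each, with TCH4, which did not pass DESeq2, at −0.27 ± 0.07) and seed storage (4 higher and 3 lower, or 4 lower adjusted over the list alone, with OLEO2 at 0.54 ± 0.06 and SESA2 at −0.73 ± 0.09). In the plastid PDC, jasmonate and salicylate lists edgeR called 0 of 19 members, against 4 at an unadjusted p under 0.05 and 0 by DESeq2. DESeq2 gave an adjusted p to 7 of 7 plastid PDC, 3 of 7 jasmonate and 2 of 5 salicylate genes. The medians of the perception and seed storage lists differed in sign from their mean or test.

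edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 1818 genes higher and 1177 lower in e2e3 in air, of which 59 and 64 differed at least 2-fold. With library size alone the split was 1185 and 1756 (median shift −0.048), DESeq2 called 1422 genes, and 1952 were called without e2e3 air replicate 2.

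**Figure D4:**
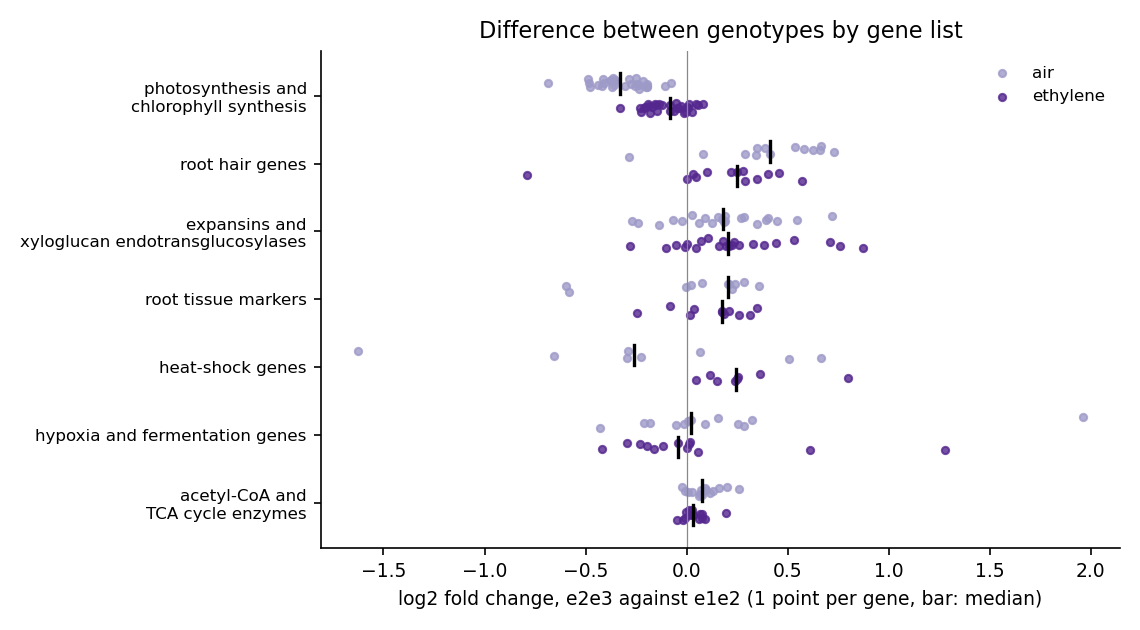
Log2 difference between e2e3 and e1e2 for each tested gene of 7 fixed lists, in air (light purple) and in ethylene (dark purple), with a bar at each median. Photosynthesis genes lie below 0 in air, with a median of −0.33, and nearer to 0 in ethylene, with a median of −0.08.

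In ethylene, E1 ALPHA was 10.9-fold higher in e2e3, the latex-protein gene MLP31 2.36-fold, PXMT1 2.13-fold, GSTF7, which has a near-identical neighbour, 2.12-fold and GH3.3 2.03-fold (n = 2 per group). Lower were mtLPD2 by 3.9-fold, FRO2 by 2.66-fold, IRT1 and the potassium channel gene SKOR each by 2.33-fold, and GRP9 by 2.25-fold. AT4G33070 was 2.43-fold higher, at 58.9 ± 1.72 against 24.3 ± 0.283 CPM. Among perception genes, EBF1 (−0.26 ± 0.05), EBF2 (−0.14 ± 0.04) and ERS1 (−0.12 ± 0.04) were lower in e2e3, or 5 of 17 adjusted over the list alone and 1 by DESeq2 (EBF1). The call on ERS1 was kept in 2 of the 8 fits that left out a library.

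Photosynthesis genes were lower in e2e3 in 13 of 30 cases in ethylene (14 lower and 1 higher adjusted over the list alone), with CAB2 at −0.33 ± 0.05, LHCA1 at −0.23 ± 0.04 and LHCB6 at −0.21 ± 0.04. Expansin and xyloglucan genes were higher in 9 of 22 cases (10 adjusted over the list alone), with EXPA8 at 0.71 ± 0.05 and XTH19 at 0.38 ± 0.04. Root hair genes were higher in 5 of 13 cases (8 adjusted over the list alone), with PRP3 at 0.45 ± 0.05, beside 6 of 11 root tissue markers, with CASP2 at 0.32 ± 0.05. Auxin genes were higher in 6 and lower in 1 of 24 cases, with WES1 at 0.26 ± 0.05. Seed storage genes were higher in 6 and lower in 1 of 16 cases, with EM1 at 0.39 ± 0.07. Mitochondrial stress markers were higher in 3 of 10 cases (5 adjusted over the list alone and 0 by DESeq2), with NAC13 at 0.25 ± 0.08. DESeq2's filter left 1 of these 3 without an adjusted p. None of these 3 passed with library size alone, and NAC13 kept its call in 5 of the 8 fits that left out a library. Hypoxia genes were higher in 1 and lower in 1 of 13 cases (2 lower adjusted over the list alone, and 1 higher by DESeq2), with LBD41 at −0.30 ± 0.10. DESeq2 gave LBD41 no adjusted p, and its call was lost with the replicate block and kept in 4 of the 8 fits that left out a library. The TCA list had 1 higher member (ACO3, AT2G05710, 0.19 ± 0.03) and the heat-shock list 1 (HSP17.6A, 0.80 ± 0.10), or 2 adjusted over the list alone. The other 8 lists were plastid PDC, ethylene response, biosynthesis, light, histone acetylation, jasmonate, salicylate and touch. In them edgeR called 0 of 79 members, against 14 at an unadjusted p under 0.05, 0 adjusted over the list alone and 1 by DESeq2. DESeq2 gave an adjusted p to only part of these members, such as 6 of 13 biosynthesis and 2 of 7 light genes, but to 7 of 7 plastid PDC genes.

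edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment called 857 genes higher and 468 lower in e2e3 in ethylene, of which 32 and 41 differed at least 2-fold. With library size alone the split was 606 and 798 (median shift −0.032), and the 1325 calls became 558 with DESeq2 (440 and 118), 711 without e1e2 ethylene replicate 1, 655 without e1e2 ethylene replicate 2 and 638 without e2e3 ethylene replicate 2.

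Wild type can be read only from the authors' own comparisons. In the authors' deposited table of 1242 genes picked for their change in wild type, ERF1 rose by 4.52 (log2) in wild type, 4.19 in e1e2 and 3.21 in e2e3, and HLS1 by 1.39, 1.08 and 1.08. In the authors' deposited table ETR2 rose by 1.69, 1.78 and 1.63, and EBF2 by 1.01, 0.85 and 0.73. IAA19 in the authors' deposited table fell less in wild type (−1.22) than in e1e2 (−2.03) and e2e3 (−1.84), as did EXPA5 (−2.34, −3.42 and −2.95). The authors' deposited table held 445 nuclear genes that were higher in wild type, with median log2 changes of 1.58 in wild type, 1.08 in e1e2 and 1.05 in e2e3, and 735 that were lower, with medians of −1.46, −1.04 and −1.04. Of these in the authors' deposited table, 392 of 444 and 401 of 445 kept the wild-type sign upward in e1e2 and e2e3, and 694 did downward in each.

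Genes picked for a large change in 1 genotype tend to show a smaller one elsewhere, so no test of a weaker response was made from that table. For scale, nuclear genes were also picked at 2-fold or more with a DESeq2 adjusted p under 0.05 in a mutant. Those from the authors' deposited table of e1e2 (1013 genes) had a median ratio of e2e3 to e1e2 changes of 0.952. Those from the authors' deposited table of e2e3 (1088 genes) had a ratio of e1e2 to e2e3 of 0.937. Against wild type, the median ratios in the authors' deposited table were 0.679 and 0.665 for genes higher in wild type and 0.677 and 0.686 for genes lower in it, in e1e2 and e2e3. The authors' deposited tables of the mutants called 1650 genes higher and 2577 lower in e1e2 and 2142 and 3055 in e2e3, at a DESeq2 adjusted p under 0.05.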

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

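The scaling test below was chosen only after its result had been seen. By edgeR's quasi-likelihood test of the difference itself (e2e3 response to ethylene minus e1e2 response, log2), 566 genes responded differently in the 2 lines, and 4 gene lists passed camera. The list medians were 0.22 for photosynthesis and chlorophyll genes, 0.36 for heat-shock genes, 0.32 for seed storage and late embryo genes and −0.21 for root hair genes. None of the 4 passed with an estimated correlation (adjusted p = 0.335 with an estimated correlation for photosynthesis, heat-shock and root hair genes, and 0.527 for seed storage genes), where 2 lists had an unadjusted p under 0.05. Their estimates were 0.482 for photosynthesis, 0.293 for seed storage, 0.044 for root hair and 0.033 for heat-shock genes. Lists with negative estimates lost calls elsewhere, so these losses do not by themselves show correlated genes. Fry called 4 lists, of which 2 were among these.

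Among called genes with a symbol, a mean of at least 5 CPM and groups that did not overlap, the 5 largest differences each way were EXPA12 (1.22), MLP31 (0.79), KIN2 (0.78), EPR1 (0.77) and SESA2 (0.74) upward and SNM1 (−0.82), CER4 (−0.81), PXMT1 (−0.79), GSTF6 (−0.79) and ATCSLB05 (−0.71) downward. Among list members, responses were higher in e2e3 for mtLPD2 (0.32), AT3G11100 (ENAP1, 0.39), LHCB2.1 (0.47), LHCA3 (0.33), CAB1 (0.30), HSP70 (0.41), HSP17.6II (1.99) and EM1 (0.31), and lower for EBF1 (−0.25), EIN2 (−0.17), AT1G12010 (−0.88), AT4G33070 (−0.69) and OLEO2 (−0.45). Of these 23 genes, KIN2, LHCB2.1, LHCA3, CAB1, HSP70 and OLEO2 passed DESeq2, mtLPD2, EBF1, EIN2 and EM1 did not, and its own filter left the other 13 without an adjusted p. KIN2 fell in e1e2 (−0.56 ± 0.04) and rose in e2e3 (0.22 ± 0.04).

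Photosynthesis genes were lower in e2e3 than in e1e2 in air (median −0.33, 29 of 30 past the test), and 21 of the 30 had a higher ethylene response in e2e3, with 9 not past the test. Both results rest on the same air libraries, so they are not separate observations. The list passed neither time when the correlation was estimated (adjusted p = 0.299 with an estimated correlation in air and 0.335 for the difference). A lower share of cotyledon tissue in the e2e3 seedlings is argued against by the storage-oil breakdown genes ICL, MLS, PCK1 and 12 others, which are also expressed mainly in cotyledons. Their median difference in air was 0.08, with 6 of 15 higher, 9 not past the test and MLS at 0.14 ± 0.03. The standard error of their mean, with genes taken as independent, was 0.02. With library size alone the photosynthesis median in air was −0.38, so the fall does not hang on the choice between these settings. Their median shift in air was only −0.048, too small to have removed the fall, so the test could not decide on scaling in general. In the same comparison 11 of 13 root hair genes and 6 of 11 root tissue markers were higher in e2e3 and none lower, but more root tissue would lower the cotyledon share, so the storage-oil genes argue against it too as the cause of the photosynthesis fall. A difference between the genotypes themselves stays open and was not tested, and each line is represented by 2 libraries in air.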

How the results depend on the processing

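The counts of called genes kept within 1.5 times their reported values under RLE factors, library size alone, both low-count filters, separate fits, a replicate block and without organellar genes (separate fits give no difference of responses). DESeq2 called 5137 genes for ethylene in e1e2 (5134 of them shared with edgeR's 7911), 220 for the difference of responses (211 shared), 1422 for the lines in air (1420 shared) and 558 in ethylene (547 shared). Its 5924 for ethylene in e2e3 and the overlap of 4066 stayed within that bound. DESeq2's own filter left 186 of the 566 edgeR calls on the difference of responses without an adjusted p, 397 of the 2995 in air and 292 of the 1325 in ethylene, and no test was made of the rest of the gap.

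Leaving out each library in turn, which leaves a group of 1 library assumed to vary like the others, gave 6327 to 7879 calls for ethylene in e1e2, 7291 to 9141 in e2e3, 240 to 545 for the difference of responses, 1952 to 2936 for the lines in air, 638 to 1586 in ethylene and an overlap of 5125 to 5516. The difference of responses fell to 263 and 240 without e1e2 ethylene replicate 1 or 2, 367 without e2e3 air replicate 1 and 242 without e2e3 ethylene replicate 2. The lines in ethylene fell to 711 and 655 without e1e2 ethylene replicate 1 or 2 and 638 without e2e3 ethylene replicate 2, and the lines in air to 1952 without e2e3 air replicate 2. These fits have fewer samples, and no other cause was tested.

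Of the lists past the test, 8 for ethylene in e1e2 became 1 with an estimated correlation, 8 in e2e3 became 1, and 14 with fry (9 up, 5 down). The 4 for the difference of responses became 0 with an estimated correlation (2 at an unadjusted p under 0.05, 4 with fry), and the 4 for the lines in air became 0 (2 at an unadjusted p under 0.05) and 11 with fry (8 up, 3 down). The perception and hypoxia lists had negative estimated correlations (−0.05 and −0.057) and still lost their calls for ethylene in both lines. Calls lost under that alternative thus cannot be put down to correlated genes alone. Fry asks another question, whether a list's own genes move one way on balance. Leaving out single libraries gave 7 to 9, 7 to 8, 3 to 5 and 3 to 6 lists.

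Of 3130 values for named genes under the alternatives, 2911 kept their direction and side of the threshold, 209 lost the call, 4 gained one and 6 changed sign, the cause of which was not tested. All 6 were values not past the test: with library size alone IAR4 (0.0544) and MAB1 (0.0363) for ethylene in e1e2 and MAB1 (0.04) and LTA3 (0.0282) in e2e3, and IAR4 in e1e2 over the single libraries left out (−0.0493 to 0.025), above 0 without e1e2 air replicate 2 or e1e2 ethylene replicate 2. Named calls held in all 8 such fits for 61 of 70 genes for ethylene in e1e2, 63 of 70 in e2e3, 10 of 23 for the difference of responses, 37 of 52 for the lines in air and 30 of 37 in ethylene.

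With replicate number as a block, 7856, 8798, 580, 2784 and 1155 genes were called, with an overlap of 6028 and 7, 8, 4 and 4 lists. No pairing by number was seen: across genes, replicate differences of 2 groups correlated at −0.03 to 0.001. Much of these differences is counting noise, so a weak pairing could have been missed. Library depth limits genes of low count most, as for ERF1 in air in e1e2 (7 counts over 2 libraries).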

Other observations

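In this part, the tests of a larger root share, of all camalexin members in a single library and of chloroplast-encoded genes, and all gene groups below, were chosen only after their results or the comparison of the lines had been seen. Iron-deficiency genes, which take up and move iron, were lower in e2e3 in air in 9 and higher in 1 of 23 cases. FRO2 differed by −2.13 ± 0.16, IRT1 by −1.82 ± 0.09, CYP82C4 by −2.49 ± 0.39, NAS2 by −1.12 ± 0.19 and the regulators bHLH39 and FRU (FIT) by −0.73 ± 0.16 and −0.49 ± 0.12 (camera adjusted p = 4.61e-06, and adjusted p = 0.0585 with an estimated correlation). DESeq2 called 5 lower and 1 higher. In ethylene, 6 were lower (camera adjusted p = 0.000869, and adjusted p = 0.0865 with an estimated correlation), against 1 by DESeq2, whose filter left the other 5 without an adjusted p. Ethylene raised 11 and lowered 4 of them in e2e3, with IRT1 at 1.31 ± 0.10 and FRO2 at 1.14 ± 0.18 (camera adjusted p = 0.00398, and adjusted p = 0.204 with an estimated correlation), and raised 8 and lowered 2 in e1e2 (camera adjusted p = 0.0838), with IRT1 at 0.71 ± 0.07 and FRO2 at 0.42 ± 0.12. The difference of responses passed for IRT1 (0.60 ± 0.12) and FRO2 (0.72 ± 0.22), which the filter of DESeq2 left without an adjusted p (list camera adjusted p = 0.0111, and adjusted p = 0.25 with an estimated correlation). This difference uses the same air libraries as the comparison in air, after which the list was made, so it partly restates that comparison.

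Among 143 groups of at least 8 genes sharing a symbol stem, ethylene lowered 13 of 15 SAUR genes (auxin-induced growth genes) in each line (medians −1.27 and −1.27), all 9 GPAT genes of cutin and lipid synthesis (−1.01 and −1.36), 19 of 25 AGP genes in each (−0.69 and −0.81), 10 and 11 of 15 KCS genes of wax synthesis (−0.58 and −0.70) and 8 of 9 TUB tubulin genes (−0.55 and −0.61). The camera adjusted p of these ran from 6.2e-09 to 0.000553, and adjusted p = 0.327 with an estimated correlation was the lowest. It raised 45 and 55 of 109 EMB genes, needed for embryos, and 8 and 11 of 13 PTAC genes of plastid transcription (camera adjusted p from 2.97e-06 to 0.0153, and adjusted p = 0.327 with an estimated correlation at the lowest). In air, all 9 RHS root hair genes were higher in e2e3 (median 0.56), as were 10 of 23 GSTU, 6 of 8 GSTF and 7 of 9 MLP genes, while 8 of 9 LHCB, 7 of 13 PTAC and 19 of 109 EMB genes were lower (camera adjusted p from 8.55e-07 to 0.000702, and adjusted p = 0.388 with an estimated correlation at the lowest). Exceptions were 1 AGP gene and 2 KCS genes that rose in e1e2, 1 KCS gene that rose in e2e3, 6 and 3 EMB genes that fell, and, in air, 1 GSTU gene lower and 1 EMB gene higher.

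Storage-oil breakdown genes rose in 6 and fell in 4 of 15 cases in e1e2 and in 4 and 3 in e2e3 (camera adjusted p = 0.504 and 0.715), MLS alone differed in response (0.26 ± 0.05, list 0.662, with median and mean of opposite sign), and 6 were higher in e2e3 in air and 4 in ethylene (camera adjusted p = 0.0139 and 0.00281, and adjusted p = 0.32 and 0.23 with an estimated correlation). Microbe-pattern response genes rose in 2 and fell in 4 of 12 cases in e1e2 and in 3 and 4 in e2e3, with CAF1a at 0.82 ± 0.14 and 1.13 ± 0.12, and 2 were higher (MYB51 and YLS9) and 1 lower (PHI-1) in e2e3 in air. In ethylene edgeR called 0 of the 12 (2 at an unadjusted p under 0.05, 0 by DESeq2, which gave 2 of them an adjusted p). The list passed camera there (adjusted p = 0.0108, and adjusted p = 0.0865 with an estimated correlation). For the difference of responses edgeR called 0 (3 at an unadjusted p under 0.05, 0 by DESeq2, which gave none of the 12 an adjusted p). Within 2 Mb of E1 ALPHA (AT1G59900), 97 of 688 tested genes (14.1%) differed between the lines in air, and near mtLPD2 (AT3G17240) 132 of 871 (15.2%), against 14.8% of all tested genes. MYC2 and F3H, of which other genes cover 98.5% and 93.8% of the exonic bases, had mean counts of 0.2 and 0.0 and were not tested, and HSP17.4 (70.9% covered) and OSR1 (42.7%) are undercounted to an unknown degree.

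Genes of camalexin and indole-derived defence, which make an antimicrobial compound, were higher in e2e3 in air in 6 of 9 cases, among them CYP71A12 (2.51 ± 0.33), PAD3 (1.18 ± 0.26), GSTF6 (1.70 ± 0.13) and CYP71A13 (0 counts in e1e2 and 34 in e2e3, at least 8.59-fold with a floor of 3 counts over the group), with a median of 1.07 with or without that bound (camera adjusted p = 8.17e-05, and adjusted p = 0.052 with an estimated correlation), although DESeq2 called 1 of the 6 and gave an adjusted p to 2. Some of these levels were low and uneven. CYP71A12 read 0.53 and 1.18 CPM in the e1e2 air libraries and 6.82 and 3.43 CPM in the e2e3 air libraries. PAD3 read 1.41 and 2.76 CPM against 5.39 and 4.33 CPM. A larger root share is not decided by its test, since the raised genes in it were picked by their rise. The largest rise of a root tissue marker past the test was 0.36, and root hair genes had a median of 0.41. The median was 1.44 in the raised camalexin genes and 1.07 in all 9. A single e2e3 air library apart from the other cannot be told apart from a difference shared by both. In the lower of them the median of all 9 members was 0.74, with a standard error of their mean of 0.28. Another test was set before its value was seen: 83.3% of the 6 raised members lay at least 1.5 times above both e1e2 air libraries in both. It decides nothing, since these members were picked by their rise. A response to microbes or handling in the e2e3 dishes cannot be told apart from an effect of the genotype, which was not tested. The reason is that microbe-pattern genes had a median of 0.11, with a standard error of their mean of 0.11. Both standard errors take genes as independent. Ethylene lowered 9 of the 9 in e2e3 (median −1.49, camera adjusted p = 5.49e-05, and 0.0426 with an estimated correlation) and 5 in e1e2 (camera adjusted p = 0.0838), with CYP79B3 at −2.25 ± 0.05 and −2.55 ± 0.06. The fall in e2e3 and the difference of responses use the same e2e3 air libraries as the comparison in air, after which the list was made. Part of both may therefore come from that choice. The response was lower in e2e3 for CYP71A12 (−2.15 ± 0.54), PAD3 (−1.68 ± 0.41) and GSTF6 and higher for CYP79B3 (0.30 ± 0.08), none by DESeq2, whose filter left 3 of these 4 without an adjusted p (list camera adjusted p = 0.0111, and adjusted p = 0.18 with an estimated correlation), and 2 members, GSTF6 and CYP79B3, were higher in e2e3 in ethylene (0.0108, and adjusted p = 0.0865 with an estimated correlation).

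Log2 fold changes of most nuclear genes in the authors' deposited table were smaller in the mutants than in wild type or of the other sign (344 of 444 genes higher and 574 of 735 lower in wild type for e1e2, 364 of 445 and 566 of 734 for e2e3), with median ratios of 0.665 to 0.686. Genes that changed more in both mutants included IAA19, IAA6, EXPA5 and EXPA8. Chance highs in wild type, kept because the genes were picked there, cannot be told apart from a weaker response. Among the 177 genes with an authors' mean count of at least 1000, the median ratios in the authors' deposited table were 0.803 in e2e3 and 0.77 in e1e2. These were nearer to 1 but below the 0.952 and 0.937 between the mutants by the authors' DESeq2 tables. The latter had no limit on the mean count, so the sets of genes are unlike. By size of the wild-type change in the authors' deposited table, the ratios were 0.716 and 0.709 (e1e2 and e2e3) at log2 changes of 1 to 1.5 and 0.623 and 0.607 at 2 or more. Wild-type libraries made, grown or treated in another way stay open too. The 60 chloroplast-encoded genes in the authors' deposited table had a median of 1.23 in wild type against −0.39 in e1e2 and 0.04 in e2e3. This decides nothing, since only genes changed at least 2-fold in wild type are listed there, so none could lie near 0 in wild type. An effect of the mutations on the response stays open and was not tested.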
